A study of Mus musculus with 19 samples.

How the data were processed

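The series holds RNA sequencing of neural progenitor cells from cortices of Mettl14 wild-type (WT) and Mettl14 conditional knockout (KO) mouse embryos. There are 4 WT and 4 KO ladder libraries, in which mRNA was separated by length into 7 bands with their own barcodes and sequenced as paired-end reads of 75 bp, and 3 standard WT libraries of single-end reads of 50 bp, per the labels. Long reads were taken on a nanopore device from native RNA and from direct cDNA, with 2 replicates per genotype and chemistry that share 1 file. Groups were taken from the sample labels, and the 2 genotypes, the 2 library types and the 2 long-read chemistries were kept apart.

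The authors quantified transcripts with kallisto, per the submitters' processing notes and the file headers, of a version not given in the sources used here. The deposited estimated counts per transcript are not whole numbers, and their totals differ between libraries. The deposited TPM values were scaled by the authors so that each file sums to the same total over its own targets. How the bands of a ladder library were combined into 1 file is not given in the sources used here. The submitters' processing notes also list STAR 2.5.4b and StringTie beside the short-read samples and minimap2 2.17 beside the long-read samples, with the genome build GRCm38 (mm10), without saying what each was used for. The long-read assemblies were deposited as transcript structures from FLAIR, of unstated version and with no abundance, and from StringTie 2.0 in its long-read mode, per the file headers, with TPM of each assembled transcript as StringTie wrote it. The ladder files hold assembled targets without a structure, which took 11.9% to 13.4% of the counts, beside annotated transcripts. They were kept in library totals and left out of genes.

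Estimated counts were summed over the transcripts of each gene in the GENCODE M21 annotation and rounded. Genes and transcripts were kept by the default of filterByExpr, scaled by TMM and tested in edgeR 4.0.16 (R 4.3.3) by quasi-likelihood tests with robust dispersion, with p adjusted by Benjamini and Hochberg and a threshold of 0.05. Levels are given as CPM, counts scaled to the library total after TMM unless stated otherwise, and changes as log2 fold changes. KO was compared with WT in ladder libraries alone, 4 against 4. WT ladder libraries were compared with standard libraries, 4 against 3, over the 105882 targets that all files share, since the target sets differed. Transcript usage was tested with diffSpliceDGE and the Simes method for each gene. In addition, a stricter count took genes with a transcript whose share moved by 10 points or more without overlap of the libraries. Shares of counts by transcript class and length were compared in exact two-sided permutation tests, adjusted over 16 classes.

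In these data, 33 gene lists for m6A factors, signalling, metabolism, cell cycle, RNA processing, neural lineages and other cell types a culture could hold were tested with camera in limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation. Beside these, fry, which asks whether the genes of a list move one way without comparing them with other genes, called 22 of the 33 lists. Members past the threshold were counted over all genes tested and adjusted over the list alone. The lists, tests, groups, first set of alternatives and the rule for naming genes were set before the data were examined. That rule took Mettl14 and the m6A writers, the 10 largest rises and 10 largest falls among genes past the threshold with an average log2 CPM of 1 or more, no overlap between the genotypes and a regular symbol, and up to 2 rises and 2 falls of each list. For transcripts it took 5 of each direction, for usage 8 genes with an average log2 CPM of 2 or more, and for the comparison of protocols 8 genes of each direction. Some genes that the rule took are not reported here, and lists and counts over all genes keep them. Genes named beyond the rule are marked in the text as chosen after their values were seen.

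Structures were compared by intron chain, the ordered set of intron ends, with an exact match. A short-read transcript counted as supported when its chain was in any WT assembly, which held for 15822 of 91579 shared multi-exon targets. A transcript counted as detected at 1 TPM or more. Transcripts per gene were counted at 10% or more of a gene of 5 TPM or more, a measure added after the data were seen. Long-read gene levels summed the TPM of StringTie transcripts that held an annotated intron of the gene, so a gene without introns is at 0. They were compared between genotypes with pseudocounts of 0.1 TPM for cDNA and 1 TPM for native RNA. Folds against a group without counts are lower bounds against a floor of 3 counts over the group (0.006597 CPM in WT ladder, 0.006819 in KO ladder and 0.07713 in standard libraries). With 1 to 3 counts the ratio is given with its 95% counting interval. Shares of long-read structures carry 95% Wilson intervals.

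Totals of estimated counts ran from 103752000 to 126922000 in WT ladder, from 104900000 to 118198000 in KO ladder and from 12084500 to 13987900 in standard libraries. Between libraries of the same group, chi-square per degree of freedom ran from 26.78 to 237.5, far above the value of 1 for counting error alone. The procedures were tested on simulated data in which 240 genes or transcripts of each test carried changes of 1.5-fold, 2-fold or 4-fold. Of such genes, 32.5%, 82.5% and 100% were found between genotypes with 3.91% of calls false, and 1.25%, 32.5% and 75% between protocols with 6.45% false. For transcripts between genotypes 1.25%, 3.75% and 55% were found with 12.7% false, and between protocols 0%, 0% and 5% with 0% false. Transcript usage found 2.5%, 35% and 87.5% with 45.7% of calls false, and the stricter count 0%, 17.5% and 72.5% with 17.2% false. Simulated lists were all found, with 0 false, but their genes were drawn independently of each other. They therefore cannot show how camera performs where the genes of a list vary together. Far fewer genes and transcripts changed in the simulations than were called in the real data, so these shares need not hold for the real calls.

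Alternatives tried were DESeq2 1.42.0 size factors and Wald tests, limma voom, no filter, offsets for transcript length, a test beyond 1.5-fold, the replicate number as a block, leaving out each library, other TPM thresholds (0.5 and 5), thinning to equal total counts, single assemblers, introns within 10 bp, 3 or more exons, and transcripts holding 5% of their gene. Added after the data were seen were autosomal genes alone, GC offsets in 20 bins, transcript length offsets for the lists, the stricter usage count, TPM rescaled to shared targets, the same after thinning, and the 15000 highest transcripts of each library. Tables were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Single length bands and raw reads were not analysed here.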

Results

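RNA was measured in mouse neural progenitor cells, the dividing cells from which the neurons and glia of the cortex arise. They were isolated from embryonic cortices of Mettl14 wild-type (WT) and Mettl14 conditional knockout (KO) mice and grown with FGF2 and EGF at 20 ng/ml each. Mettl14 is the partner of Mettl3 in the enzyme complex that writes N6-methyladenosine (m6A) into mRNA. In Ladder-seq, mRNA is parted by length, here into 7 bands, and each band receives its own barcode before sequencing. There were 4 WT and 4 KO libraries of this kind, called ladder libraries here, and 3 standard WT libraries that were not parted by length. Total estimated counts, rounded to 6 digits, ranged from 103752000 to 126922000 in the WT ladder libraries, from 104900000 to 118198000 in the KO ladder libraries and from 12084500 to 13987900 in the standard libraries. Nanopore reads of native RNA and of direct cDNA came from 2 replicates per genotype, pooled into 1 assembly per genotype, chemistry and assembler, so their values carry no replicate error. The labels do not name separate cultures for the replicates, which may therefore be technical. Pearson correlations of gene levels (log2 CPM) were 0.9845 to 0.9904 among WT ladder libraries, 0.9865 to 0.9917 among KO ladder libraries and 0.9405 to 0.9544 between the genotypes, over genes and not over independent replicates.

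The first comparison asks how loss of Mettl14 changes gene expression. Mettl14 (ENSMUSG00000028114, GRCm38 chromosome 3, from 123368297 to 123386108) fell from 29.0 ± 4.24 to 7.95 ± 0.944 CPM (read counts scaled to library size, mean ± SD, n = 4 per genotype). On the log2 scale it fell by 1.87 (SE 0.133). The 4 WT libraries held 28.6, 23.2, 32.6 and 31.7 CPM, and the 4 KO libraries 7.03, 9.25, 7.59 and 7.92 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes, this fall had an adjusted p of 5.4e-07. Long reads showed which part of the transcript was missing. The WT assemblies by StringTie held a Mettl14 transcript with all 11 annotated exons, at 19.8 TPM (transcript abundance scaled to the assembly) in native RNA and 1.62 TPM in cDNA. None of the 3 native and 4 cDNA transcripts that StringTie assembled for the KO covered exons 7, 8 or 9 (from 123374745 to 123374886, from 123373970 to 123374062 and from 123372557 to 123372673), and their TPM summed to 13.7 and 1.68. These exons hold 352 bp, which leaves a remainder of 1 when divided by 3. In 2 of the native KO transcripts (7.74 and 3.36 TPM) and 1 of the cDNA KO transcripts (0.713 TPM), the first exons were instead joined to an exon 44766 bp downstream of the gene, which ended at 123323531 within the oppositely oriented gene Sec24d. In WT cDNA, a fragment of 4 exons at 0.0662 TPM also lacked exons 7 to 9. The FLAIR assembly of KO cDNA held 1 Mettl14 transcript, without these exons. The FLAIR assembly of native KO RNA listed the full-length transcript, but it shared 22686 transcript names with the WT one, 12342 of them named after single reads, so these 2 assemblies were not independent. Both of them, WT and KO, also held a read-named Mettl14 transcript without exons 7 to 9.

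**Figure D1:**
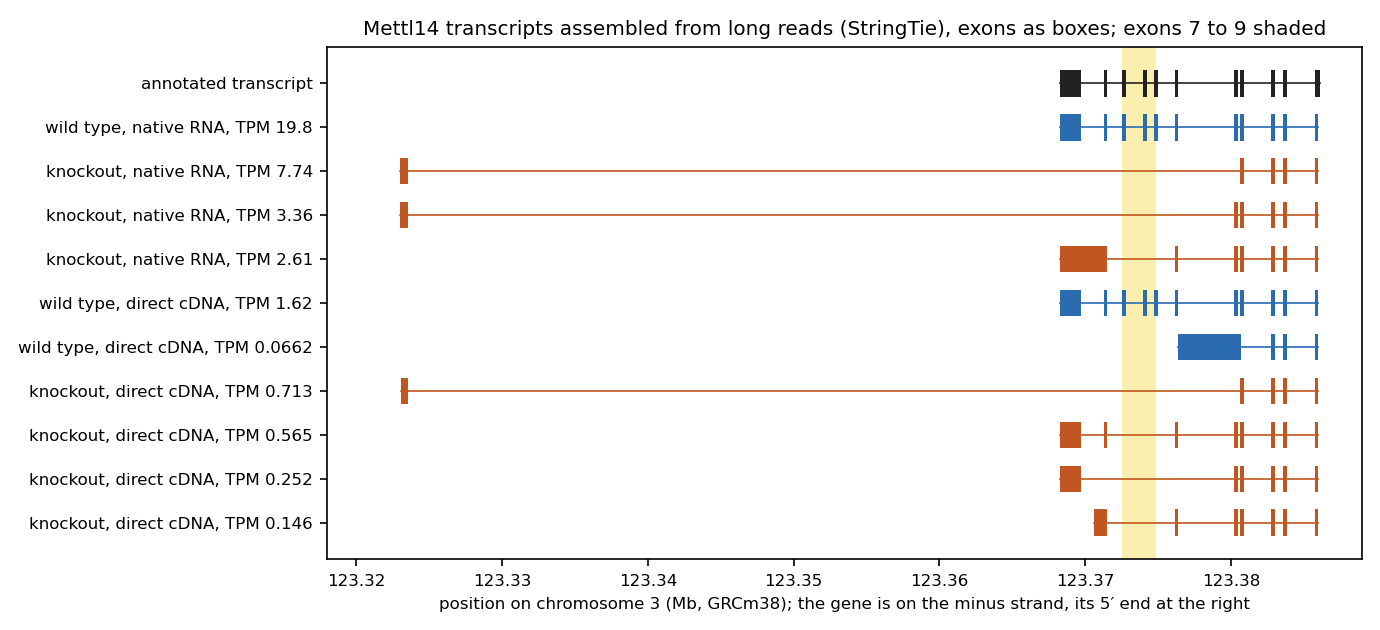
Mettl14 transcripts assembled by StringTie from long reads, along chromosome 3 in Mb (GRCm38), with exons as boxes, WT in blue, KO in orange and the annotated transcript in black. The WT transcripts at 19.8 and 1.62 TPM cross the shaded exons 7 to 9, which no KO transcript covers.

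Among other genes of m6A writing, most rose while Mettl3 fell slightly. Rbm15 (chromosome 3, from 107325421 to 107333673), which guides the complex to its target RNAs, rose from 11.7 ± 1.84 to 58.6 ± 1.44 CPM (n = 4 per genotype). Its paralog Rbm15b rose from 35.1 ± 10.5 to 128 ± 13.1 CPM, and Wtap, the adaptor of the complex, rose from 48.3 ± 2.99 to 94.4 ± 5.71 CPM. Mettl16, a separate methyltransferase, rose by 0.94 on the log2 scale, Zc3h13 by 0.81 and Cbll1 by 0.37. Virma rose by 0.42 (adjusted p = 0.033), a call that was lost without KO replicate 1 (0.095), KO replicate 2 (0.064), WT replicate 3 (0.080) or WT replicate 4 (0.067). Mettl3, the catalytic subunit, fell from 25.7 to 21.4 CPM, a log2 change of -0.27 (adjusted p = 0.036), a call lost without KO replicate 1 (0.083), 2 (0.12) or 4 (0.065) or WT replicate 3 (0.072) or 4 (0.11). It was lost under several other settings too, with adjusted p from 0.053 to 0.24, and in the test beyond 1.5-fold. Of the 9 writer genes tested, 7 rose and 2 fell, and all 9 passed when adjusted over the list alone. Mettl14, the gene knocked out by design, is 1 of the 2 that fell, and the list was not tested without it. The list as a whole had an adjusted p of 0.051 in camera, which compares a list with all other genes. It passed at 0.037 without KO replicate 1, 0.048 without KO replicate 3, 0.041 without KO replicate 4, 0.0475 without WT replicate 2, 0.046 without WT replicate 3 and 0.040 without WT replicate 4. It also passed with DESeq2 size factors (0.0496), with GC offsets (0.041) and with no filter (0.0014). It did not pass in camera with an estimated correlation (adjusted p = 0.32), nor without KO replicate 2 or WT replicate 1.

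Among genes of higher expression, the largest rise was that of Serpinb11 (chromosome 1, from 107361198 to 107380475), a serpin-family gene, from 0.0105 ± 0.0122 to 11.02 ± 0.689 CPM. Cyba, a subunit of the NADPH oxidase, rose from 0.129 ± 0.0666 to 16.6 ± 3.49 CPM, and Grin2c, an NMDA receptor subunit, from 0.389 ± 0.189 to 22.1 ± 3.62 CPM. Tmem132c rose by 6.96 on the log2 scale, Abca8a, a lipid transporter, by 6.35, Gdf10, a BMP-family ligand, by 5.72, and Bgn, an X-linked matrix proteoglycan, by 8.05. The processed pseudogene Rps6-ps4 went from 0.759 ± 1.21 to 146 ± 83.9 CPM, a log2 change of 7.55, or 9.92 without WT replicate 3, and reads of such copies can come from their parent genes. The largest fall was that of Sncb (chromosome 13, from 54758860 to 54766595), which encodes the synaptic protein beta-synuclein, from 21.9 ± 2.78 to 0.587 ± 0.129 CPM. H19 (chromosome 7, from 142575529 to 142578143), an imprinted non-coding RNA, fell from 61.9 ± 9.82 to 1.69 ± 0.143 CPM. Pdgfra (chromosome 5, from 75152292 to 75198215), the PDGF receptor of oligodendrocyte precursors, fell from 100 ± 17.3 to 5.24 ± 0.530 CPM. Sox10 (chromosome 15, from 79154908 to 79165240), a transcription factor of the same lineage, fell from 16.2 ± 5.83 to 0.932 ± 0.106 CPM. Further falls, as log2 changes, were those of the lactate exporter Slc16a3 (-3.86), the lipase Liph (-3.86), the iron reductase Cybrd1 (-3.997), Smim20 (-3.86) and the protocadherin Pcdhb9 (-3.77). Each group had n = 4, and the adjusted p in edgeR was 2.5e-09 for Serpinb11, 2.6e-09 for Sncb, 1.5e-09 for H19, 5.1e-09 for Pdgfra and 4.1e-07 for Sox10. In the native RNA assemblies, Pdgfra went from 59.3 to 0 TPM, Sox10 from 28.3 to 0, Sncb from 6.68 to 0, Cyba from 6.51 to 66.4 and Serpinb11 from 0 to 34.8.

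**Figure D2:**
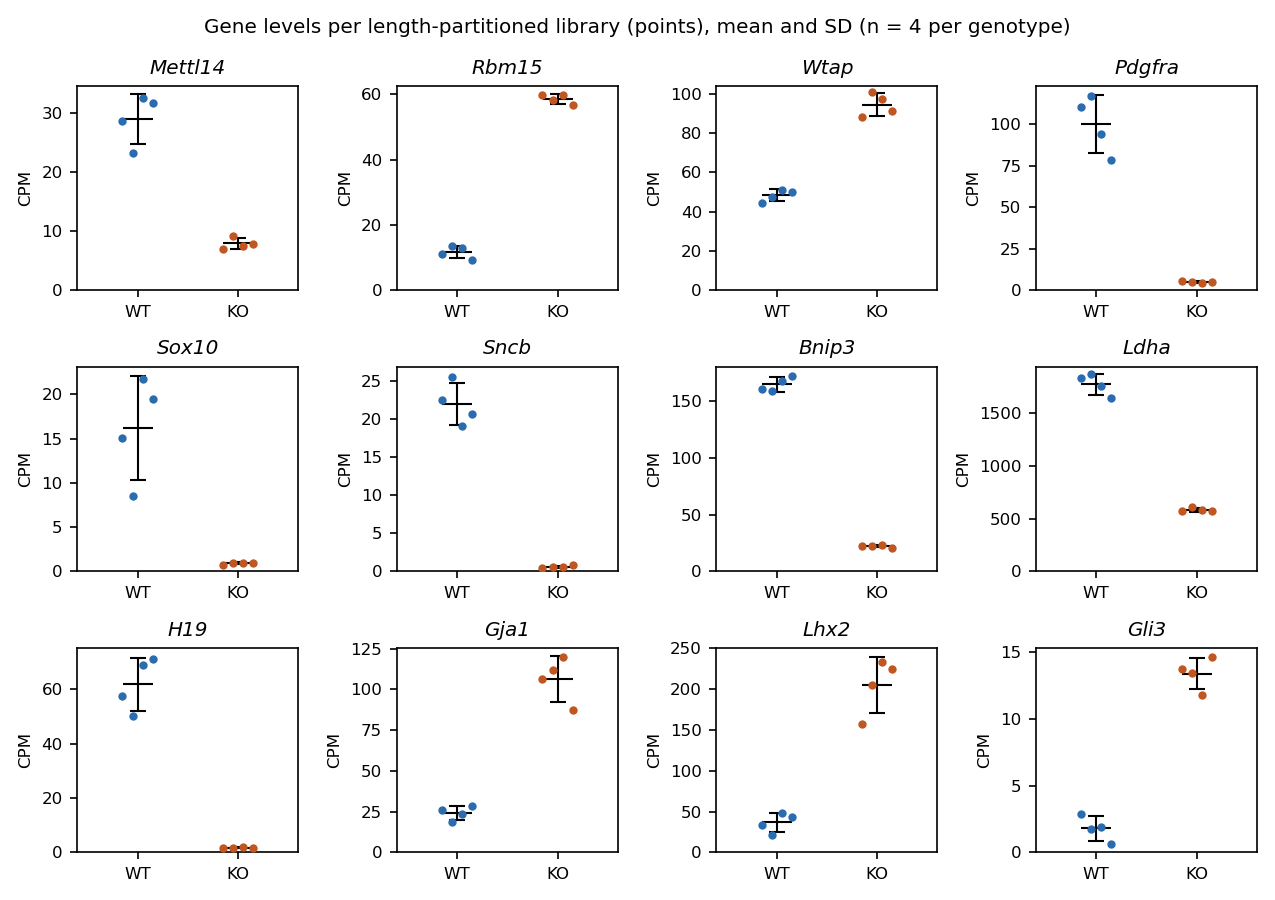
Levels of 12 genes (CPM) in each ladder library, with points for libraries and the mean and SD for each genotype (n = 4). The 4 KO libraries of Mettl14 lie from 7.03 to 9.25 CPM and the 4 WT libraries from 23.2 to 32.6 CPM.

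Genes of glycolysis and of the response to low oxygen were lower in the KO. Of 20 tested, 19 fell and 0 rose, and all 20 passed when adjusted over the list alone. Bnip3 (chromosome 7, from 138890836 to 138909519), a hypoxia-induced regulator of mitochondrial turnover, fell from 165 ± 6.36 to 22.2 ± 1.03 CPM (n = 4 per genotype), and Ankrd37, another hypoxia target, from 10.95 ± 0.0964 to 1.31 ± 0.372 CPM. Ldha, which makes lactate, fell from 1777 ± 98.9 to 586 ± 17.4 CPM, and the glycolytic enzyme Pgk1 and the angiogenic factor Vegfa changed by -1.84 and -1.68 on the log2 scale. Hexokinase Hk2 held 29.95 CPM in WT and 24.95 CPM in KO (adjusted p = 0.055, or 0.015 without WT replicate 3 and 0.011 with GC offsets). The list median was -1.40 on the log2 scale (camera adjusted p = 1.1e-16, and adjusted p = 0.038 with an estimated correlation). Neuronal genes were lower as well, with 14 of 19 falling, 3 rising and 18 past the threshold when adjusted over the list alone (camera adjusted p = 4.0e-05, and adjusted p = 0.046 with an estimated correlation). Tubb3, the tubulin of young neurons, fell from 27.0 ± 1.46 to 10.4 ± 0.973 CPM, and Dcx, a microtubule protein of migrating neurons, the synaptic Snap25 and the neurofilament gene Nefl changed by -1.45, -2.37 and -3.35 on the log2 scale. The glutamate transporter Slc17a6 was at 0 in every WT library and at 0.141 ± 0.00634 CPM in the KO. Ldha, Pgk1, Vegfa, Hk2, Tubb3 and Dcx were chosen after their values were seen.

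Oligodendrocyte-lineage genes fell in 8 of 14 cases and rose in 2, with 10 past the threshold when adjusted over the list alone (camera adjusted p = 2.7e-04, and adjusted p = 0.063 with an estimated correlation). Besides Pdgfra and Sox10, the myelin gene Mbp fell from 3.36 ± 0.328 to 0.556 ± 0.0701 CPM and the precursor proteoglycan Cspg4 from 143 ± 27.6 to 74.3 ± 7.30 CPM. Olig1, a transcription factor of the lineage, rose from 939 ± 175 to 1580 ± 125 CPM, and its neighbour Olig2 held 505 and 443 CPM (adjusted p = 0.46, or 0.034 without WT replicate 2). Astrocyte genes rose in 11 of 16 cases and fell in 4, with 15 past the threshold when adjusted over the list alone (camera adjusted p = 0.032, and adjusted p = 0.32 with an estimated correlation). That list call was lost with GC offsets (0.054) and without WT replicate 1 (0.054). The gap junction gene Gja1 (chromosome 10, from 56377330 to 56402513) rose from 24.2 ± 4.19 to 106 ± 14.02 CPM, Gfap, the intermediate filament of astrocytes, by 0.86 on the log2 scale, the water channel Aqp4 by 1.17, S100b by 1.38 and the glutamate transporter Slc1a2 by 1.15. Aldh1l1, an enzyme of folate metabolism, fell by 1.48 and the chaperone gene Clu fell by 1.40, and Apoe held 4026 and 4144 CPM (adjusted p = 0.84). Radial glia and stem cell genes went both ways, 6 up and 6 down of 24, with 12 past the threshold when adjusted over the list alone (camera adjusted p = 0.91). Their median was 0.049 and their mean -0.031. Lhx2, a patterning factor of the cortex, rose from 36.8 ± 11.6 to 205 ± 34.3 CPM and Emx2 from 31.7 ± 8.12 to 76.0 ± 6.48 CPM. Nestin (Nes) rose by 1.15, whereas the glial fatty acid binder Fabp7, vimentin (Vim) and the receptor phosphatase Ptprz1 changed by -0.73, -0.54 and -1.47. Pax6 held 18.4 and 18.5 CPM (adjusted p = 0.94) and Sox2 64.3 and 66.0 CPM (adjusted p = 0.96). Mbp, Cspg4, Olig2, Gfap, Aqp4, S100b, Slc1a2, Apoe, Nes, Fabp7, Vim, Ptprz1, Pax6 and Sox2 were chosen after their values were seen, and all groups had n = 4.

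Imprinted genes, which are expressed from 1 parental copy, fell in 8 of 16 cases and rose in 5, with 13 past the threshold when adjusted over the list alone (camera adjusted p = 2.9e-04, and adjusted p = 0.055 with an estimated correlation). The falls included the maternally expressed Meg3 (log2 change -4.91) and Rian (-3.17) and the paternally expressed Dlk1 of the same cluster (-1.62). Peg10 rose by 1.46, Grb10 by 1.46 and Igf2r by 1.01. Markers of meningeal fibroblasts rose in 7 of 10 cases and fell in 0, with 8 past the threshold when adjusted over the list alone (camera adjusted p = 2.7e-04, and adjusted p = 0.070 with an estimated correlation). They stayed at low levels, with the collagen gene Col3a1 at 0.0131 ± 0.00671 CPM in WT and 2.20 ± 0.181 CPM in KO, and the mesenchymal factor Twist1 at 0.162 ± 0.0333 and 3.39 ± 0.426 CPM. Matrix and adhesion genes rose in 11 of 21 cases and fell in 2, with 13 past the threshold when adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.51 with an estimated correlation). The basement membrane collagens Col4a1 and Col4a2 rose by 2.06 and 1.71, and the laminin gene Lama1 fell by 1.74. Sex-linked genes differed by genotype in all 5 cases, 4 up and 1 down, with 5 past the threshold when adjusted over the list alone (camera adjusted p = 1.4e-11, and adjusted p = 0.061 with an estimated correlation). The Y-linked Ddx3y went from 0.0129 ± 0.0150 to 4.39 ± 0.632 CPM, Eif2s3y by 7.90 on the log2 scale, Uty by 5.29 and Kdm5d by 4.71, while Xist, the RNA of the inactive X, fell from 173 ± 31.4 to 55.9 ± 11.5 CPM. In the long reads, Ddx3y went the other way, from 15.2 to 4.64 TPM in native RNA and from 2.01 to 0.503 TPM in cDNA. Rian, Dlk1, Igf2r, Twist1, Uty and Kdm5d were chosen after their values were seen, and all groups had n = 4.

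Transcripts of the mitochondrial genome fell in 12 of 19 cases and rose in 0, with 12 past the threshold when adjusted over the list alone (camera adjusted p = 2.9e-04, and adjusted p = 0.34 with an estimated correlation). The transfer RNA genes mt-Tc and mt-Ty changed by -2.28 and -2.05 on the log2 scale at levels under 1 CPM. The cytochrome gene mt-Cytb, chosen after its values were seen, fell from 23.8 ± 4.18 to 14.8 ± 0.755 CPM. Replication-dependent histone genes fell in 32 of 66 cases and rose in 4, with 37 past the threshold when adjusted over the list alone (camera adjusted p = 0.0037, and adjusted p = 0.80 with an estimated correlation). Among them, the linker histone Hist1h1b fell from 5.93 ± 1.44 to 1.29 ± 0.159 CPM. Ribosomal RNA took 6.98% ± 1.96 of the estimated counts in WT and 2.77% ± 0.222 in KO libraries (adjusted p = 0.1143 in an exact permutation test). Regulators of neural splicing fell in 10 of 21 cases and rose in 2, with 12 past the threshold when adjusted over the list alone (camera adjusted p = 0.032, and adjusted p = 0.35 with an estimated correlation). That list call was lost with GC offsets (0.098). Elavl3, a neuronal RNA-binding protein, fell from 21.9 ± 2.67 to 4.55 ± 0.848 CPM and the splicing factor Srrm3 fell by 1.69. All groups had n = 4.

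**Figure D3:**
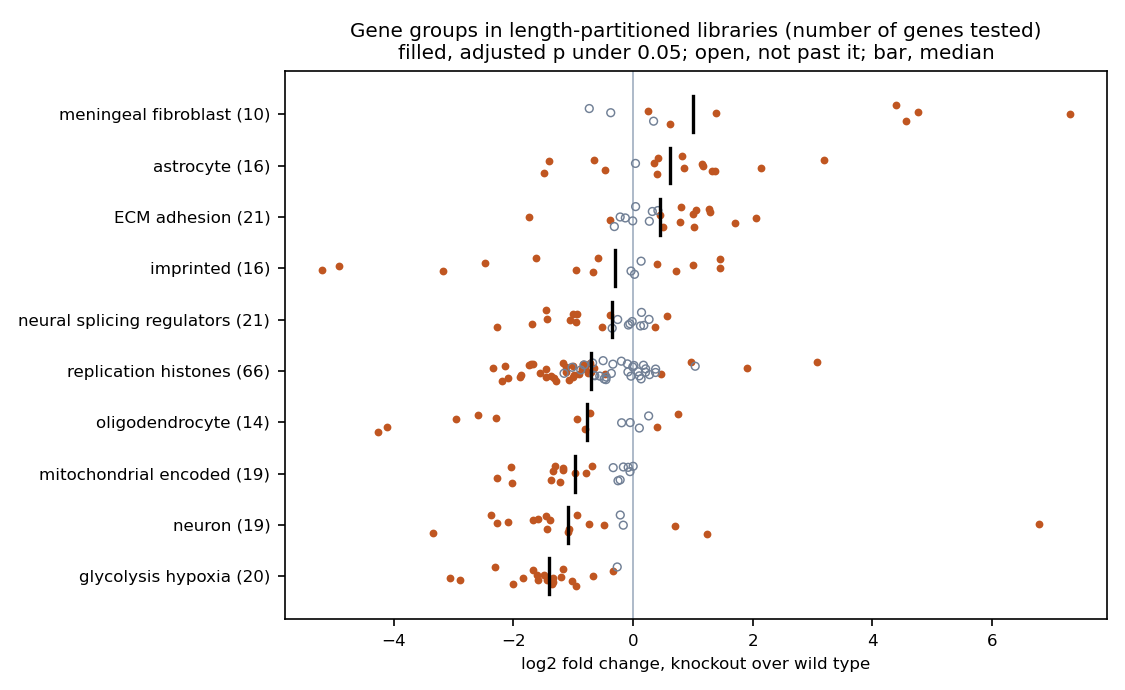
Log2 fold changes, KO over WT, of the genes in 10 lists, with the number of genes tested beside each list, filled points for genes past the adjusted threshold, open points for the others and a bar at the median. The glycolysis and hypoxia list has its median at -1.40, and the meningeal list reaches the farthest to the right with Col3a1 at 7.30.

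The remaining lists did not pass camera, although members of each changed. With no filter, 5 of them passed camera, namely Notch, Wnt and Shh genes (adjusted p = 0.0055), endothelial and mural genes (0.0075), p53 targets (0.021), SR and hnRNP factors (0.040) and G1/S genes (0.043). Among m6A readers and erasers, 4 of 14 rose and 4 fell (8 adjusted over the list alone, camera adjusted p = 0.87), with the reader Ythdf2 up by 1.29 on the log2 scale and Igf2bp2 at -1.18. Among genes of Notch, Wnt and Shh signalling, 6 of 17 rose and 2 fell (7 adjusted over the list alone, 0.074, or 0.037 without WT replicate 4), with the Shh effectors Gli3 and Gli2 up by 2.89 and 2.22 and Hhip at -0.55. Among p53 targets, 1 of 18 rose and 8 fell (9 adjusted over the list alone, 0.075, or 0.0475 without WT replicate 2), where the pro-apoptotic Pmaip1 fell by 2.01. Among CDK inhibitors, 1 of 8 rose and 4 fell (5 adjusted over the list alone, 0.25), with Cdkn2b at -1.29 and Cdkn1a at -1.02. G1/S genes rose in 11 of 22 cases and fell in 3 (14 adjusted over the list alone, 0.32), and G2/M genes rose in 5 and fell in 6 of 22 (11 adjusted over the list alone, 0.77). The cyclin gene Ccnd2 fell by 1.01, E2f1 rose by 0.96, and the proliferation marker Mki67, chosen after its values were seen, held 181 and 156 CPM (adjusted p = 0.30). FGF and EGF response genes rose in 9 of 16 cases and fell in 2 (12 adjusted over the list alone, 0.49), with the feedback inhibitor Il17rd up by 1.89 and Ccnd1 at -0.69. Interferon-response genes rose in 8 of 24 cases and fell in 4 (13 adjusted over the list alone, 0.58), with Isg15 up by 1.09 and Ifit2 at -0.88. Immediate early genes rose in 6 and fell in 9 of 24 (15 adjusted over the list alone, 0.77), and integrated stress genes rose in 6 and fell in 7 of 17 (13 adjusted over the list alone, 0.62), with Klf2 up by 1.83 and Stc2 at -1.61. Cholesterol synthesis genes rose in 7 and fell in 1 of 18 (8 adjusted over the list alone, 0.68), with Dhcr7 up by 0.86. Histone modifiers rose in 10 and fell in 5 of 30 (15 adjusted over the list alone, 0.68), SR and hnRNP splicing factors rose in 10 and fell in 2 of 24 (12 adjusted over the list alone, 0.32), polyadenylation factors rose in 6 and fell in 6 of 19 (14 adjusted over the list alone, 0.94), and RNA decay factors rose in 3 and fell in 2 of 20 (3 adjusted over the list alone, 0.80). Ribosomal protein genes rose in 8 and fell in 5 of 77 (5 adjusted over the list alone, 0.84), with Rpl34 down from 296 to 32.7 CPM, a gene with pseudogene copies. Proneural and intermediate progenitor genes rose in 3 and fell in 2 of 11 (5 adjusted over the list alone, 0.80), with Hes6 up by 0.90 and the Notch ligand Dll3 at -1.45. Ventral interneuron genes rose in 3 and fell in 2 of 5 (5 adjusted over the list alone, 0.77), with the patterning factors Sp8 up by 2.92 and Gsx1 at -2.63. Endothelial and mural genes rose in 8 and fell in 2 of 10 (10 adjusted over the list alone, 0.11) and microglial genes rose in 3 of 5 (3 adjusted over the list alone, 0.53), with the pericyte receptor Pdgfrb up by 4.12 and the microglial Csf1r up by 1.91 at levels of 1.39 and 0.184 CPM in the KO. The 2 endothelial and mural genes that fell were Flt1, from 4.34 to 0.323 CPM, and Kdr, at -0.45 on the log2 scale.

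In all, 10016 of 18687 genes tested differed between the genotypes, 4926 higher and 5090 lower in the KO, of which 3808 changed 2-fold or more (1866 up, 1942 down). For 48.96% of the genes the libraries of the 2 genotypes did not overlap, against 2.857% expected by chance for 4 against 4 libraries. On autosomes, 9672 of 18068 genes differed, and on the X chromosome 326 of 591, of which 199 were lower in the KO. Of the autosomal genes that were called, changed 2-fold or more and were assembled in both genotypes, 682 of 868 (78.6%, 95% Wilson interval 75.7 to 81.2) went the same way in the native RNA assemblies and 837 of 1100 (76.1%, 73.5 to 78.5) in the cDNA assemblies, against 56.0% and 56.2% of assembled genes that were not called. Of the 33 lists, 11 passed camera with its preset correlation and 2 with an estimated one. All libraries of a genotype share whatever else differed between its cultures, and intervals and floors here cover counting error only, since PCR reads are not independent molecules.

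Single transcripts showed all-or-none differences. Nfe2l1-204, from the gene of a transcription factor of proteasome genes, had no counts in the WT and 24.6 ± 5.10 CPM in the KO, at least 3658-fold higher against a floor of 3 counts over the group. In the same way, transcripts of the heat shock factor gene Hsf1 (Hsf1-201), of Rai1 (Rai1-202) and of Arhgef25 (Arhgef25-201) were at least 1993-fold, 1457-fold and 1334-fold higher in the KO. The same held for the decay-prone transcript Abhd16a-207, at least 1157-fold higher. In the other direction, Acly-201, from the gene for ATP citrate lyase, had 26.4 ± 7.26 CPM in the WT and no counts in the KO, at least 3881-fold lower. Cspg5-204, Srp68-203, Acad11-202 and Exoc1-201 were at least 2511-fold, 2313-fold, 2285-fold and 1404-fold lower in the KO. In edgeR's quasi-likelihood test, 22044 of 59136 transcripts differed (n = 4 per genotype). Estimated counts divide reads between similar transcripts, so a count of 0 does not show that a transcript was absent.

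Within genes, the share held by each transcript shifted as well. In Pdgfra, the share of Pdgfra-202 rose from 20.8% ± 2.71 to 88.6% ± 12.1 while Pdgfra-201 went from 75.9% to 8.82%. In the non-coding gene AA465934, the share of AA465934-203 rose from 3.81% ± 0.944 to 89.1% ± 1.32, and the intron-retaining AA465934-201 fell from 61.1% to 5.27%. Exoc1-202, of a subunit of the exocyst, rose from 10.3% ± 11.9 to 93.0% ± 1.57, Egln2-202, of an oxygen-sensing prolyl hydroxylase, from 22.8% ± 9.26 to 82.7% ± 2.38, and Parp9-203 from 36.4% ± 9.99 to 94.8% ± 5.68. Lrp8-201, of a reelin receptor, fell from 80.5% ± 10.6 to 19.2% ± 14.6 and Tdrd7-202 from 60.1% ± 20.7 to 2.19% ± 0.738. In Cul2, a cullin of a ubiquitin ligase, the decay-prone Cul2-202 fell from 66.7% ± 10.2 to 9.14% ± 8.01 and the coding Cul2-205 rose from 31.1% to 88.4%. The gene-level adjusted p in edgeR's diffSpliceDGE ran from 1.1e-12 for AA465934 to 0.0049 for Pdgfra (n = 4 per genotype). Altogether 1791 of 10532 genes changed in transcript usage, and 806 of them had a transcript whose share moved by 10 points or more without overlap between the genotypes. The count was 4466 with limma voom and diffSplice, and 744 over transcripts holding 5% or more of their gene. Among the transcripts that moved by 10 points or more without overlap, retained-intron forms rose in 34 cases and fell in 70, and forms subject to nonsense-mediated decay rose in 44 and fell in 54. Of the 1791 genes, 1075 also differed at gene level, where 969.8 would overlap if the 2 sets were independent. On simulated data in which 240 of 10258 genes changed, 45.7% of the genes this usage test called were false, and 17.2% in the stricter form. Far more genes were called in the real data, so these shares need not hold there.

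The shares of some broad classes of RNA parted the genotypes without overlap, although none passed after adjustment. Protein-coding transcripts held 70.03% ± 2.05 of the estimated counts in WT and 76.0% ± 0.895 in KO (n = 4 per genotype), retained-intron transcripts 2.58% ± 0.133 and 2.37% ± 0.0642, and transcripts subject to nonsense-mediated decay 2.73% ± 0.124 and 2.44% ± 0.103. Ribosomal RNA held 6.98% in WT and 2.77% in KO on average, with 9.40%, 6.99%, 6.92% and 4.599% in the 4 WT libraries and 2.58%, 2.66%, 2.76% and 3.08% in the 4 KO libraries. In a two-sided exact permutation test each of these 4 classes had a raw p of 0.02857, the smallest that 70 assignments of 4 against 4 libraries allow. After adjustment over 16 classes the smallest p was 0.1143, so none of the 16 passed in the exact permutation test. A class at the smallest raw p could pass only if many others reached it too. The adjusted test therefore says nothing about the size of these 4 differences. Length classes had adjusted p from 0.152 to 1 in the same exact test.

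The second comparison sets WT ladder libraries against standard WT libraries, and so asks what partitioning by length changes. Mettl14 held 31.2 ± 0.746 CPM in the 3 standard libraries and 36.3 ± 5.54 CPM in the 4 WT ladder libraries (adjusted p = 0.23 in edgeR). Interferon-response genes were near absent from the standard libraries and abundant in the ladder libraries, with 23 of 24 higher and 0 lower (23 adjusted over the list alone, camera adjusted p = 2.6e-48, and adjusted p = 0.0028 with an estimated correlation). Isg15 (chromosome 4, from 156199424 to 156200818), a ubiquitin-like protein of the antiviral response, was at 0.249 ± 0.0105 CPM in standard and 530 ± 59.9 CPM in ladder libraries (adjusted p = 2.0e-07). Bst2, which tethers viruses to the cell, was at 5.73 ± 3.32 and 784 ± 95.9 CPM. The antigen-presenting genes B2m and H2-D1 stood at 37.2 and 26.0 CPM in standard and at 1957 and 2055 CPM in ladder libraries. On a scale of library totals over shared targets without TMM, the median of the 24 genes was 1.11, 0.935 and 1.71 CPM in the 3 standard libraries, 87.0 to 101 CPM in the WT ladder libraries and 94.6 to 108 CPM in the KO ladder libraries. Among the genes of the largest rise, Oas1a, an antiviral sensor, was at least 858.9-fold higher in ladder libraries, Apol9a at least 508.7-fold and Tgtp2 at least 298.6-fold, against a floor of 3 counts over the 3 standard libraries. Ifit3 and Ifi27l2a had 2 counts in the standard libraries, which gives ratios of 8911 (95% counting interval 2467 to 73580) and 8480 (2348 to 70030). The WT long reads did not show these levels, with Ifit3, Oas1a, Apol9a and Tgtp2 at 0 TPM in both chemistries, Ifi27l2a at 0 TPM in cDNA and 2.88 in native RNA, and Isg15 at 0.0946 and 0 TPM. Isg15, Bst2, B2m and H2-D1 were chosen for this comparison after their values were seen.

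**Figure D4:**
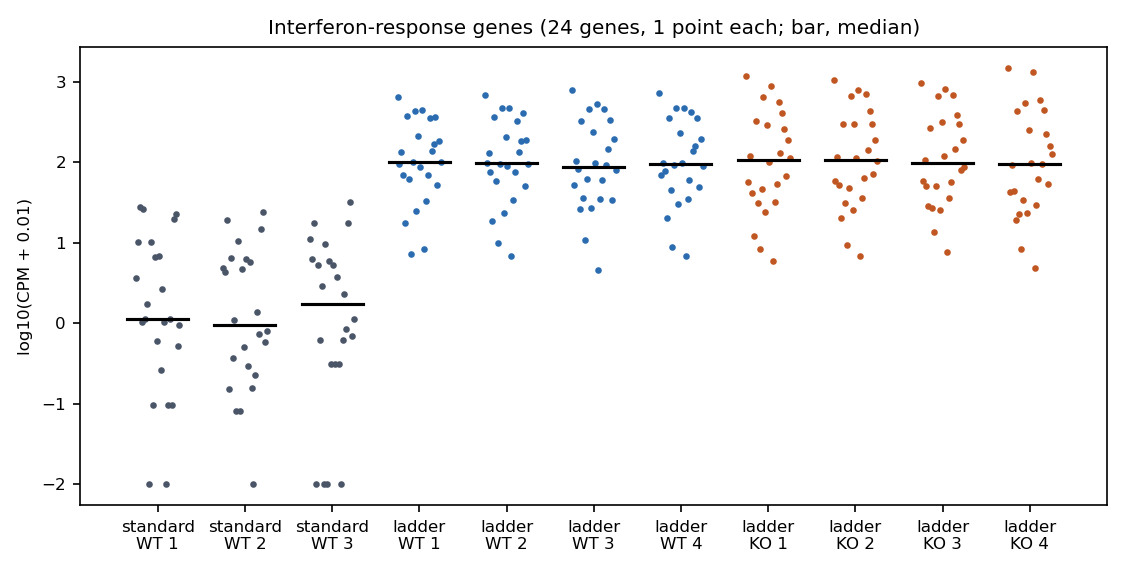
Levels of the 24 interferon-response genes on a log10 scale of CPM (library totals over shared targets, without TMM) in each standard and ladder library, with 1 point per gene and a bar at the median. The medians of the 3 standard libraries lie from 0.935 to 1.71 CPM and those of the 8 ladder libraries from 87.0 to 108 CPM.

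Transcripts of the mitochondrial genome went the opposite way, lower in ladder libraries in 12 of 13 cases (12 adjusted over the list alone, median -5.43 on the log2 scale, camera adjusted p = 5.9e-42, and adjusted p = 0.061 with an estimated correlation). The respiratory chain gene mt-Nd1 was at 2097 ± 210 CPM in standard and 34.4 ± 6.52 CPM in ladder libraries, and mt-Co1 at 4988 ± 551 and 174 ± 22.5 CPM. Ribosomal protein genes were higher in ladder libraries in 61 of 77 cases and lower in 11 (72 adjusted over the list alone, camera adjusted p = 2.5e-13, and adjusted p = 0.34 with an estimated correlation), with Rplp0 at 1032 and 4189 CPM but Rpl3 at 751 and 19.4 CPM. Replication-dependent histones were lower in 50 of 65 cases and higher in 5 (58 adjusted over the list alone, camera adjusted p = 4.0e-08, and adjusted p = 0.36 with an estimated correlation). Neuronal genes were lower in 16 of 19 cases (adjusted p = 0.0059, and adjusted p = 0.53 with an estimated correlation), and G2/M genes, such as the topoisomerase gene Top2a at 611 ± 155 and 287 ± 54.7 CPM, in 17 of 22 (adjusted p = 0.0054, and adjusted p = 0.51 with an estimated correlation). Astrocyte genes were higher in 11 of 15 cases (adjusted p = 0.0035, and adjusted p = 0.31 with an estimated correlation), with the lipid carrier Apoe at 48.6 ± 20.7 and 5028 ± 350.1 CPM and Sparcl1, a synapse-promoting protein, at 185 and 1734 CPM. Glycolysis genes were higher in 12 of 20 cases (adjusted p = 0.010, and adjusted p = 0.54 with an estimated correlation). Several genes of high expression lost nearly all their counts on the shared targets. Ndst1 and Ndn had 139 and 115 CPM in standard libraries but 1 count in the ladder libraries, which gives ratios of 54570 (95% counting interval 9790 to 2156000) and 46640 (8367 to 1843000). Nnt (ENSMUSG00000116207, which overlaps another gene of that name) was at least 3099-fold and Cdr1 at least 3063-fold lower in ladder libraries. Phkg1 went from 9366 ± 4154 to 3.36 ± 0.257 CPM, Ppia, which encodes cyclophilin A, from 914 to 21.4 and Atp5f1 from 215 to 3.32, although native WT long reads held Ppia at 978 TPM and Atp5f1 at 847 TPM. Ndn, Nnt and Cdr1 were at 0 TPM in both WT long-read chemistries, and Ndst1 at 0.927 TPM in cDNA and 0 in native RNA. Those levels count only assembled transcripts with an annotated intron. A gene without introns is therefore at 0 by construction, and its 0 does not show that the transcript was absent. Among pseudogenes, whose reads can come from their parents, Rpl19-ps11 was at least 6086-fold and Bnip3l-ps at least 383.4-fold higher in ladder libraries, as was the gene Exosc6 by at least 505-fold. Eif4a-ps4, Tpt1-ps3, Pgam1-ps2 and Ptges3-ps were at least 42810-fold, 27220-fold, 4821-fold and 3966-fold lower. The genes from mt-Nd1 to Sparcl1, and Phkg1, Ppia and Atp5f1, were chosen after their values were seen.

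Across all genes, 9862 of 16131 differed between WT ladder and standard libraries in edgeR's test, 4967 higher and 4895 lower in ladder libraries, and 6784 of them by 2-fold or more. For 62% of genes the libraries of the 2 protocols did not overlap, against 5.714% expected by chance for 4 against 3 libraries. At transcript level, 23177 of 48881 differed. Further lists passed camera as lower in ladder libraries, all lost with an estimated correlation (adjusted p from 0.29 to 0.51): m6A readers and erasers (13 of 15 lower), m6A writers (6 of 9), neural splicing regulators (14 of 21), SR and hnRNP factors (14 of 24), G1/S genes (14 of 22), histone modifiers (15 of 30) and FGF and EGF response genes (8 of 16). These tests of lists between protocols were added after the data were seen. The 2 protocols also differed in read layout, read length, sequencing run and the set of quantified targets, which differed among the standard libraries too. The labels do not say whether the protocols shared cultures. An effect of partitioning therefore cannot be told apart from these differences. The shared targets held 73.8% to 79.2% of the counts of WT ladder libraries and 96.9% to 99.4% of those of standard libraries. How many calls depend on the targets left out was not tested. Gene levels correlated at 0.7803 to 0.8355 between ladder and standard WT libraries and at 0.9074 to 0.9618 among standard libraries (Pearson on log2 CPM, over genes).

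Fewer transcripts were detected per ladder library, and a higher share of them, though a lower number, had a matching long-read structure. At 1 TPM or more, 17032 ± 778 transcripts were detected in the WT ladder libraries (n = 4) and 34069 ± 423 in the standard libraries (n = 3), a difference with p = 0.0286 in a two-sided exact permutation test over 35 assignments, the smallest it allows. Thinning the total counts of all libraries to the smallest total gave 17265 and 34066, which does not equalise depth over shared targets. On average 67.7% ± 1.55 of the detected multi-exon transcripts in ladder libraries, and 41.2% ± 0.125 in standard libraries, had all their introns in a WT long-read assembly (exact permutation p = 0.0286, two-sided). At the mean level of each group these were 11277 of 16676 and 13948 of 34533 transcripts. Among the 15000 most abundant transcripts of each library, the shares were 70.4% ± 0.276 and 63.4% ± 0.868 (exact permutation p = 0.0286). Rescaling TPM to the 105882 targets that all libraries share gave 22332 and 34770 detected transcripts, since those targets hold 44.8% to 54.8% of the TPM of WT ladder libraries and 89.9% to 99.4% of that of standard libraries. Thinning and rescaling together gave 22692 and 34770. With this rescaling, long-read support was 57.2% ± 1.31 and 39.6% ± 0.297 (exact permutation p = 0.0286), a gap of 17.57 points in place of 26.53. Among shared targets, ladder libraries had 1.64 ± 0.00952 transcripts per gene that held 10% or more, against 2.09 ± 0.0228 (exact permutation p = 0.0286). The leading transcript held 79.3% ± 0.304 of its gene in ladder libraries and 70.4% ± 0.570 in standard ones (exact permutation p = 0.0286). These values rest on 6267 to 6969 genes in ladder and 9709 to 10195 in standard libraries, and leave out the assembled targets, which hold counts in ladder libraries, so the gene sets and targets are not alike.

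**Figure D5:**
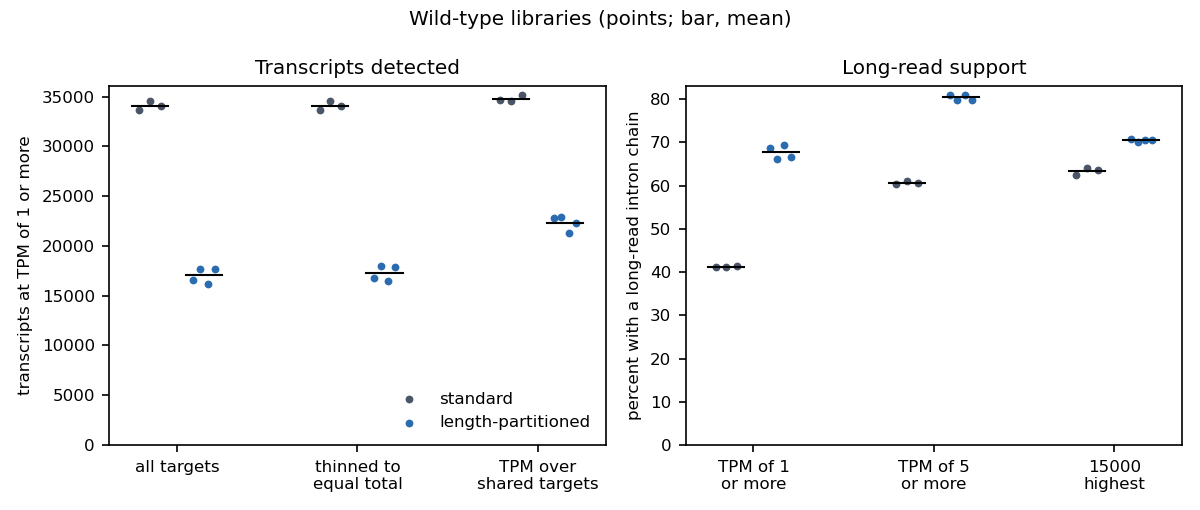
Left, the number of transcripts detected in each WT ladder and standard library under 3 ways of scaling, and right, the percentage of detected transcripts whose introns all match a WT long-read assembly, at 1 TPM, at 5 TPM and for the 15000 highest, with points for libraries and bars for means. Ladder libraries lie at 17032 detected transcripts and 67.7% supported, standard libraries at 34069 and 41.2%.

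Long-read assemblies were compared by the structures they share. In cDNA, FLAIR assembled 45682 transcripts for WT and 39091 for KO, and StringTie 57876 and 54882. In native RNA, FLAIR gave 24491 and 23430, and StringTie 20979 and 19095. The share of multi-exon transcripts whose introns match an annotated transcript was 54.9% (95% Wilson interval 54.3 to 55.6) for WT cDNA by FLAIR and 55.5% (54.9 to 56.2) for KO cDNA, and 55.1% (54.4 to 55.8) and 53.9% (53.1 to 54.6) for native RNA by StringTie. The cDNA assemblies by FLAIR had 12751 intron chains in common between genotypes, which is 58.1% of those in the KO and 54.4% of those in the WT. By StringTie, 43.9% of the KO chains were shared with the WT in cDNA and 56.2% in native RNA. The native assemblies by FLAIR, which were not independent, shared 97.4% of the KO chains. Between FLAIR and StringTie on the same WT cDNA reads, 13892 chains were shared, 59.2% of those by FLAIR.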

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

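The tests of embryo sex, GC content, length partitioning, microglia and long-read levels below were chosen only after the results they concern were seen, whereas the counts of other splits were planned.

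The KO and WT ladder libraries differed in 10016 genes. Of the 35 splits of the 8 libraries into 4 and 4, 1 split, the real one, gave as many, and the highest other gave 1 gene. The same held for 22044 transcripts (1 of 35 splits, highest other 7) and 1791 genes of altered usage (1 of 35, highest other 84). Chance in the grouping of libraries is argued against, but 1 of 35 is the smallest share these splits allow. Every other split also mixes the genotypes within its groups, which can lower its calls, so chance is not excluded. A difference in embryo sex is argued against as the whole account, since Y-linked Ddx3y was higher in the KO in ladder libraries and lower in native long reads, yet 78.57% (lower 95% bound 75.72%) of the autosomal genes that were called, changed 2-fold or more and were assembled in both genotypes went the same way in both. GC bias is argued against as the whole account, since GC offsets left 10032 genes called, among them 9033 of the 10016 (90.19%) and 0 in the opposite direction. Part of the calls did depend on these offsets, as 7 of 164 followed genes and 2 lists lost their call. The log2 change also went with GC content (rho 0.207, not tested). Such offsets remove any change that goes with GC content, whatever its cause, and only the 81.9% of called genes with a GC value were corrected. What stays open is an effect of Mettl14 loss itself, which may account for the pattern as a hypothesis, along with culture differences that the design confounds with genotype.

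Interferon-response genes were far higher in ladder than in standard libraries of the same genotype. A selective capture of transcripts by length is argued against, since the median log2 change over members with an annotated length was 6.9 against an upper bound of 0.733 for 10000 lists matched on length. Microglia in the ladder cultures are argued against, since 7.14% of microglial markers (1 of 14) reached 10 CPM, and P2ry12 stood at 1.20, Trem2 at 0.241 and Csf1r at 0.0567 CPM in WT ladder libraries (library totals over shared targets, without TMM); no sort or gate is described in the labels. In WT long reads, 66.7% of the 21 members with several exons and 20 CPM or more in WT ladder libraries were assembled (45.4% to 82.8%, Wilson), against 99.2% of genes within 2-fold between protocols. Of 79 genes that were 16-fold or more higher in ladder libraries, 53.2% were assembled (42.3% to 63.8%). The low share may therefore not be particular to this list, whose members can be among the 79. An interferon response in the ladder cultures may account for the pattern as a hypothesis, but it was not tested. Read layout, sequencing run, the set of quantified targets and perhaps culture also differ between the protocols.

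Of the genes with several exons and 20 CPM or more in standard libraries, 124 were 16-fold or more lower in ladder libraries. They were among 9862 genes that differed between the protocols (1 of 35 splits gave as many, highest other 1). For 23177 transcripts it was also 1 of 35, with 0 as the highest other. Chance in the grouping is argued against but not excluded, since the other splits mix the protocols and 35 splits allow no smaller share. The median WT cDNA long-read level of the 124 genes was 0.604 TPM. In 10000 random sets of genes matched on ladder level, the median had an upper bound of 0. This was predicted if the ladder quantification assigned reads of the 124 genes to other targets. In sets matched on standard level the lower bound was 1.79, as predicted if the ladder cultures held less of these transcripts. The genes were chosen for a low ladder and a high standard level, so a level between the 2 bounds may follow from that choice. The test therefore cannot decide, and the 2 explanations both stay open.

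Single libraries stood apart from the other 3 of their group in 21 of 365 groups of 4 tested, and chance flags about 1 in 20 groups. In KO replicate 1, processed pseudogenes held 0.985% of counts (others 0.822 to 0.849), Gdf10 5.92 CPM (7.15 to 7.21), Il17rd 46.4 (37.3 to 37.9), Srsf2 143 (156 to 158), mt-Tc 0.0426 (0.0304 to 0.0318), Cspg4 85.2 (69.9 to 71.3) and Sox11 145.5 (125 to 127.5). In KO replicate 3, Grin2c held 27.5 CPM (19.5 to 20.8), Dcn 0.233 (0.149 to 0.154) and Gsx1 2.69 (2.09 to 2.18). In KO replicate 4, Sncb held 0.780 CPM (0.511 to 0.536) and Clu 32.6 (39.4 to 40.3). In WT replicate 1, Col3a1 held 0.0231 CPM (0.00922 to 0.0106) and Rpl10 192 (118 to 130.5). In WT replicate 2, Kmt2a held 9.13 CPM (5.39 to 5.77). In WT replicate 3, Rps6-ps4 held 2.56 CPM (0 to 0.358), Isg15 480.0 (399.7 to 409.9), Igf2bp2 20.0 (28.6 to 29.1) and Tubb3 29.2 (26.2 to 26.4). In WT replicate 4, Dusp4 held 41.2 CPM (30.3 to 31.5) and Vegfa 374.9 (260.2 to 269.1).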

How the results depend on the processing

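Most results kept their direction and their side of the threshold, and when single genes, transcripts, classes, lists and overlaps of long-read assemblies were each compared with each alternative other than leaving out a library, 1922 comparisons stayed the same, 76 were weaker, 10 stronger, 11 (all overlaps of assemblies) moved and 1 reversed. The alternatives of GC offsets, autosomal genes, length offsets for lists, the stricter usage count, rescaled TPM (also after thinning) and the 15000 highest transcripts were chosen after the data were seen. Of 164 genes followed between genotypes, 164 stayed as they were under limma voom, 162 under each of DESeq2's Wald test and size factors, 160 under transcript length offsets, 156 under GC offsets and 157 with no filter. Most of these genes were named because they passed the main threshold with large changes, so these counts need not hold for other genes. A test beyond 1.5-fold ended 42 calls, since it asks for more. Kmt2a alone reversed, from -0.51 to 0.076 on the log2 scale with transcript length offsets; its WT replicate 2 stood apart, and the cause was not tested. Tested beyond 1.5-fold, 4211 of 10016 genes and 9899 of 22044 transcripts were left, since smaller changes no longer count. Usage calls rose from 1791 to 4466 with limma voom and diffSplice, and fell to 744 over transcripts holding 5% of their gene, where 7654 instead of 10532 genes were tested, and to 806 with the stricter count. Of the 33 lists, 17 passed with no filter and 2 with an estimated correlation, against 11; the cause of the first was not tested. The share of KO intron chains found in WT cDNA by FLAIR moved from 58.1% to 59.88% with introns within 10 bp, which allows more matches. With the replicate number as a replicate block, 9949 genes, 18250 transcripts, 1572 usage genes and 12 lists were called between genotypes (with the m6A writers at an adjusted p of 0.035), and 7521 genes and 10853 transcripts between protocols; the cause was not tested, and the same replicate number did not pair libraries (correlations of deviations from -0.0233 to 0.0536 between genotypes, against 0.28 for WT replicate 2 with KO replicate 1). Leaving out 1 library gave 9005 to 9960 genes and 17946 to 19903 transcripts between genotypes, 1355 to 1539 usage genes, 10 to 13 lists, and 8582 to 10796 genes and 18893 to 26753 transcripts between protocols. The difference in detected transcripts (ladder minus standard) ran from -17259 to -16754 and that in long-read support from 25.99 to 27.04 points when 1 library was left out. With 3 against 3 or 4 against 2 libraries the exact permutation test cannot go below 0.1 or 0.0667, so these say nothing about the call. The gap in support fell to 17.57 points with rescaled TPM and 7.053 points for the 15000 highest transcripts. Depth limits how low a level can be bounded (0.006597 CPM in WT ladder and 0.07713 CPM in standard libraries), and its effect on the tests of single transcripts was not varied.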

Other observations

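The values in this paragraph were chosen after they were seen, whereas the test in the next was planned. At 0 in all 8 ladder libraries but at 10 CPM or more in all 3 standard libraries stood 112 transcripts, of 10858 at that level in standard libraries, and 55 of 10179 stood the other way in the WT ladder libraries. In the cDNA assemblies, 43.5% to 48.4% of transcripts had a single exon, against 18.3% to 27.8% in native RNA. Sox11, a transcription factor of young neurons chosen after its values were seen, rose from 81.0 ± 7.99 to 131 ± 9.61 CPM in the KO (n = 4 per genotype, adjusted p = 2.2e-04 in edgeR).

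One hypothesis, written before its result was seen, was that genes with few exon junctions per kb of transcript, where m6A is thought to be laid down more often, rise in the KO. Over 14759 genes, Spearman's rho of the log2 change with junctions per kb was -0.066, across genes that are not independent replicates. Of the 35 splits of the 8 libraries, 15 gave a rho as far from 0, and the highest other was 0.106, so the data did not bear the hypothesis out. For other measures of the same genes, rho was 0.207 with GC content, -0.0304 with transcript length, 0.0422 with the longest internal exon and -0.0114 with the last exon, none of them tested.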
